A study of Mus musculus with 6 samples.

How the data were processed

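RNA was sequenced from 6 libraries of A2Lox.cre mouse embryonic stem cells carrying a doxycycline-inducible Flag-Lef1 transgene, harvested on day 3 of embryoid body culture. Per the labels, 3 libraries (minus_Dox, numbered 1, 3 and 4) had no doxycycline and 3 (plus_Dox, numbered 1, 2 and 3) had it for 24 h, and total RNA was treated with DNase, captured on oligo-dT beads, fragmented and reverse transcribed with random primers. Groups were taken from the sample titles. The submitters' processing notes name TopHat2 2.0.8, Bowtie, Picard, Cufflinks 2.0.2, Cuffdiff and the mouse build mm9, without giving each a role. The gene annotation is not given in the sources used here.

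The deposited file is 1 table with the column layout of Cuffdiff's gene-level output. Per the file headers it holds, for each of 36699 rows, an FPKM value for minus_Dox and for plus_Dox, each computed by the authors over the 3 libraries of the group, and a log2 fold change of plus_Dox over minus_Dox. The deposited test statistic is a score without a fixed range, and the p-value and q-value beside it are those of the authors' own test. For tested rows with a finite fold change, each p-value was checked to equal the two-sided normal tail of the statistic (0 differences above 1e-05). In the same rows the log2 fold was the log2 ratio of the FPKM values within 0.0014. The q-values were checked to be Benjamini-Hochberg values over all tested rows. The authors tested 18114 rows. Of the others, 18116 are marked as not tested, 368 as failed, 98 as too high in depth and 3 as too low. Rows too high in depth list 0 FPKM in 1 or both groups (both for 50, plus_Dox alone for 41, minus_Dox alone for 7), including genes that every cell uses such as Gapdh, so these values were not read as absence. A value of 0 in 1 group occurred in 284 tested rows, none of which passed, and these have no finite fold change. A spreadsheet had turned 22 gene symbols into dates, and 465 rows name several genes.

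The design fixed before the data were examined foresaw 2 cases, a model fitted here to values of single libraries, or the authors' own test where the table holds only group values. The table has 0 columns of single libraries, so the second case applied, with a q-value threshold of 0.05 and no minimum fold. No model could be fitted to single libraries, so values carry no standard deviation. The SE of a log2 fold is its size divided by the size of the authors' statistic. The authors' counting does not show how reads shared between near-identical copies or overlapping genes were divided, and such genes are uncertain. The depth of the libraries is unknown, since FPKM values of pooled groups keep no read counts, and no counting interval was computed.

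Gene lists (30, fixed before the data were examined) covered Wnt targets, ligands and partners of Lef1, germ layers and cell types that embryoid bodies or their feeder layer could hold, signalling responses, stress, cell cycle, metabolism, histones, housekeeping and mitochondrial genes. For each of the 29 lists with at least 3 tested members, the number of calls was compared with that of all other tested rows by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists. This test treats genes as independent, although members of a list can vary together, so its p-values describe these libraries and are likely too small. The median difference of log2(FPKM + 1) was placed among 10000 random lists of the same size drawn within 20 bins of mean expression, and its percentile describes the list in these libraries. This scale understates the change of low genes, and medians in log2 fold are those of the deposited folds. Genes were named by a rule fixed before the data were examined: Lef1, the 10 largest rises and 10 largest falls among calls with at least 5 FPKM in the higher group, for each list up to 5 calls with the largest fold and at least 1 FPKM in the higher group, and for lists without a call the 2 members with the highest mean. Rows that join several genes were named only as members of a list. Not every gene or list that the rule selects is printed here. Names outside this rule are said to have been chosen after their values were seen.

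Alternatives fixed before the data were examined were q-value thresholds of 0.01 and 0.1, a minimum of 2-fold, minima of 1 and 5 FPKM in the higher group, pseudocounts of 1 and 0.1, random lists not matched on expression, and a median-ratio scaling, which subtracts the median log2 fold of tested rows with at least 1 FPKM. A correction for transcript composition was added after the data were examined. GC content and length came from the longest basic transcript of each gene symbol in GENCODE vM21 (assembly GRCm38), used for these properties only and not for coordinates. Of the tested rows 16658 (92.0%) had both properties, 1370 of them through an older symbol. The log2 fold was fitted by least squares on cubic splines of GC content and log2 length with 6 knots each and their product, with folds limited to 2 in either direction, over rows with at least 1 FPKM. The fitted trend was subtracted, and the authors' SE and a normal test with Benjamini-Hochberg adjustment over these rows gave new calls.

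These steps were tested on simulated data for this comparison, with 200 of 16658 genes changed by known folds and noise drawn from the authors' SE. Without a trend, 86.4% of 4-fold, 67.2% of 2-fold and 16.2% of 1.5-fold changes were recovered in the right direction, and 4.4% of 113 calls were wrong. With the observed trend added and counted as no change, 92.9% of 1956 calls were wrong before trend removal and 4.4% of 113 after it. The added trend had the form of the fit that removes it, so this outcome was set in advance. It gives no error rate for the deposited calls. Of 200 simulated lists of 18 genes without an effect, 3.5% had a median outside the middle 95% of random lists. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0, and figures matplotlib 3.10.9.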

Results

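Gene expression was measured by RNA sequencing of polyadenylated RNA in day 3 embryoid bodies, the floating aggregates that mouse embryonic stem cells form when they begin to differentiate. The cells were A2Lox.cre, a line built for placing a doxycycline-inducible transgene next to Hprt on the X chromosome, and the transgene here encoded Flag-tagged Lef1, a DNA-binding partner of beta-catenin in the Wnt pathway. Doxycycline (Dox) was given for 24 h before harvest to 3 libraries (plus_Dox, numbered 1, 2 and 3) and withheld from 3 others (minus_Dox, numbered 1, 3 and 4). The comparison of the groups addressed which genes respond to induced Lef1. The authors' deposited table holds 1 FPKM value per gene and group (sequenced fragments relative to transcript length and library size). The spread between libraries therefore enters here only through the authors' own test, and the sequencing depth of each library is unknown. The standard error (SE) given with a log2 fold is the one implied by the authors' test statistic. The labels do not say whether the libraries came from separate cultures, so any spread between them may be technical. How the authors' test estimated that spread cannot be seen here. The SE and q-value of a gene therefore need not reflect how that gene itself varied between these libraries.

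Lef1 itself was induced. In the authors' deposited table it rose from 7.56 FPKM in minus_Dox to 51.0 FPKM in plus_Dox, a 6.75-fold rise with a 95% interval of 5.21 to 8.74 (log2 fold 2.75, SE 0.19, q listed as 0). The Lef1 row covers chromosome 3 from 130813388 to 130927274 in mm9, the build named in the submitters' processing notes, and sums transgene and endogenous transcripts. Hprt, a purine salvage enzyme gene on the X chromosome (50341313 to 50374836), rose 14.3-fold, from 2.82 to 40.4 FPKM in the authors' deposited table (log2 fold 3.84, SE 0.19, q listed as 0). The 16 other tested genes with at least 1 FPKM that lie within 1 Mb of Hprt, a set chosen after the Hprt value was seen, had a median log2 fold of 0.04, with 5 rises and 2 falls. The median near 0 therefore hides changes in both directions. Of all tested rows, 12.2% were called. The largest rises near Hprt were in Cxx1c (log2 fold 2.21, SE 0.43) and Rps2-ps13 (1.82, SE 0.38) in the authors' deposited table. The falls were in Phf6 (log2 fold -0.92, SE 0.17) and Fam122b (-0.95, SE 0.24) in the authors' deposited table. Neither passed after the trend removal described below.

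Beyond Lef1 and Hprt, the 10 largest rises among single genes with at least 5 FPKM included signalling genes of the early embryo. The authors' deposited table gives Fgf8, a growth factor of the primitive streak, at 4.06 and 51.7 FPKM (12.7-fold, log2 SE 0.23). It gives Nodal, the ligand that patterns the streak, at 5.14 and 37.0 FPKM (7.21-fold, SE 0.17), and Tdgf1, the Nodal co-receptor Cripto, at 31.3 and 190.5 FPKM (6.09-fold, SE 0.15). The other 5 were Dynlt1e, a dynein light chain gene with near-identical copies (1.53 to 18.1 FPKM), the ribosomal protein pseudogene Rpl35a-ps3, and the predicted genes Gm7671, Gm14958 and Gm6834, whose reads can be shared with near-identical copies and whose implied SE was above 1 in log2 units. Among the 10 largest falls, rows that join several genes set aside, the authors' deposited table lists Lars2, the mitochondrial leucyl-tRNA synthetase gene (257 to 62.1 FPKM, log2 fold -2.05, SE 0.18), and Cmah, a sialic acid hydroxylase gene (24.5 to 8.15 FPKM, log2 fold -1.59, SE 0.17). The same part of the authors' deposited table holds the zinc finger gene Zfp808 (9.51 to 2.94 FPKM, log2 fold -1.69, SE 0.21). Others among these falls were Gm10311, Gm8129, Gm13051, Gm13151, B630005N14Rik and AA987161, with log2 folds from -1.88 to -1.40. Of these, Gm10311 (-1.23), Gm13051 (-0.64) and Gm13151 (-0.62) did not pass after the trend removal described below, and AA987161 has no value there. Zfp808 (-1.04) and Cmah (-1.14) still passed after it with smaller folds, and Lars2 passed at -2.21.

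Of 18114 genes tested by the authors, 2210 passed a q-value of 0.05 in the authors' deposited table, 1626 of them higher and 584 lower in plus_Dox. At least 2-fold changes made up 491 of the calls, 345 up and 146 down. The split between rises and falls depended on the scaling of the groups: the median log2 fold over 12240 tested genes with at least 1 FPKM was 0.20, and after subtraction of this shift 1701 genes passed, 616 higher and 1085 lower. Fold changes also followed the composition of the transcripts. Across 11596 genes, the log2 fold correlated with transcript GC content (Spearman's coefficient 0.65) and with transcript length (-0.47), where genes are not independent replicates. Median GC content was 55.8% for the rises, 41.0% for the falls and 49.8% for genes that did not pass, and median transcript length was 1529, 4937 and 3064 nt. When a smooth trend on both properties was removed, a step chosen after the data were examined, 366 genes passed, 207 higher and 159 lower. Of the 2127 authors' calls with both properties known, 266 passed again in the same direction. Calls kept after this removal are therefore given beside the deposited ones.

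**Figure D1:**
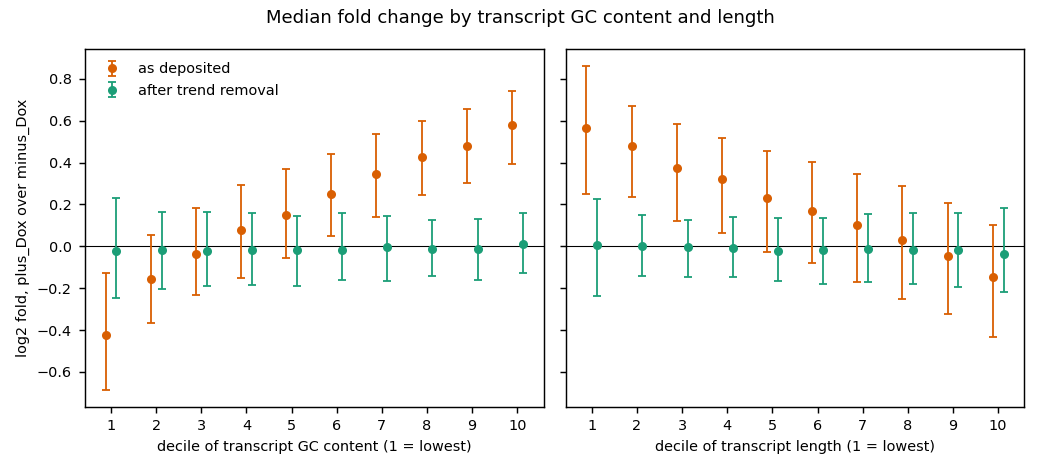
Median log2 fold of plus_Dox over minus_Dox (points) with the lower and upper quartiles (bars) in deciles of transcript GC content and of transcript length, over 11596 tested genes with at least 1 FPKM. As deposited, the median runs from -0.42 in the lowest to 0.58 in the highest GC decile and from 0.57 to -0.15 with length, and after trend removal it stays within 0.04 of 0.

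Genes of the primitive streak, the site where mesoderm and endoderm form, rose together. The 5 largest rises among members with at least 1 FPKM in the higher group in the authors' deposited table were Fgf8, T (Brachyury, the mesoderm transcription factor; 0.381 to 4.76 FPKM, 12.5-fold, log2 SE 0.42), Wnt5b (0.339 to 3.17 FPKM, SE 1.01, q = 0.017), Wnt3, the ligand that initiates the streak (0.250 to 2.16 FPKM, 8.63-fold, SE 0.26), and Nodal. Of 18 tested members of this list, 14 rose, 1 fell and 3 did not pass, with the same counts when q was adjusted over the list alone. The median log2 fold was 1.73, or 1.53 relative to the median of all genes. The streak regulators Eomes (7.83 to 18.9 FPKM), Mixl1 (0.307 to 0.886 FPKM) and Evx1 (0.0906 to 0.887 FPKM), named after their values were seen, were among the rises in the authors' deposited table. The fall was in Cer1, which encodes a secreted antagonist of Nodal, BMP and Wnt (8.02 to 5.26 FPKM, log2 fold -0.61, SE 0.21, q = 0.031). The list held more calls than the other tested genes (Fisher's exact test, two-sided, adjusted p = 3.1e-10 over 29 lists). Its median difference of log2(FPKM + 1), the scale on which all lists were ranked, was 1.26 and lay above those of all 10000 random lists of matched expression. Of the 14 rises, 12 were kept after trend removal, as was the fall of Cer1. Wnt5b and Cyp26a1 were the exceptions, the latter named after its value was seen.

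Feedback and direct targets of Wnt/beta-catenin signalling rose as well. In the authors' deposited table Sp5, a transcription factor gene that Wnt signalling switches on, went from 0.0615 to 1.48 FPKM (24.1-fold, log2 SE 0.41). Axin2, the negative-feedback gene of the pathway, went from 1.11 to 5.32 FPKM (4.80-fold, SE 0.32), the receptor gene Tnfrsf19 from 0.497 to 3.66 FPKM (7.37-fold, SE 0.24), Sp8 from 0.323 to 1.18 FPKM (SE 0.34) and the inhibitor gene Nkd1 from 0.534 to 1.48 FPKM (SE 0.23), all with q-values in the authors' deposited table of at most 3.2e-06. Of 24 tested members, 10 rose, 1 fell and 13 did not pass (11 rises and 1 fall when adjusted over the list alone), with a median log2 fold of 0.51, or 0.31 relative to all genes. The excess of calls passed (Fisher's exact test, adjusted p = 0.00034), the median difference of log2(FPKM + 1), 0.29, stood at percentile 99.8 of random lists, and 8 rises and the fall were kept after trend removal. Most of these genes were expressed at low levels: only 6 members reached 5 FPKM, of which Axin2 rose and Fzd7, a receptor gene named after its value was seen, fell, and the excess did not pass among them (Fisher's exact test, adjusted p = 0.50).

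Wnt ligand, receptor and inhibitor genes moved in both directions. Wnt8a showed the largest rise of the list in the authors' deposited table, from 0.119 to 3.63 FPKM (30.5-fold, log2 SE 0.34), and the receptor genes Fzd10 (0.444 to 2.01 FPKM, 4.53-fold, SE 0.24) and Ror2 (0.962 to 2.75 FPKM, 2.86-fold, SE 0.21) rose with Wnt3 and Wnt5b. Of 31 tested members, 12 rose, 4 fell and 15 did not pass (14 rises and 4 falls adjusted over the list alone), more calls than elsewhere (Fisher's exact test, adjusted p = 1.6e-06). The falls were in Fzd4, Fzd7, Ror1 and Cer1, the first 3 named after their values were seen, and 6 rises and 2 falls were kept after trend removal. The list's median log2 fold was 0.49, and its median difference of log2(FPKM + 1), 0.22, stood at percentile 99.0 of random lists. Among its 10 members with at least 5 FPKM, however, 1 rose and 2 fell, the median stood at percentile 24.8 and the excess did not pass (Fisher's exact test, adjusted p = 0.60). Of the other Tcf/Lef factors and their cofactors, 11 were tested: the corepressor gene Tle4 fell (18.3 to 10.3 FPKM, log2 fold -0.83, SE 0.19, q = 0.00051) and Aes rose (35.5 to 57.9 FPKM, log2 fold 0.71, SE 0.18, q = 0.0017) in the authors' deposited table. After trend removal the fall of Tle4 was kept and Aes stood at 0.04.

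Genes of the Nodal/TGF-beta response, 5 of which are also in the streak list, followed the same direction. Besides Nodal and Tdgf1, the authors' deposited table shows rises of the feedback inhibitor genes Lefty2 (2.74 to 11.5 FPKM, 4.19-fold, SE 0.29) and Lefty1 (11.4 to 31.4 FPKM, 2.75-fold, SE 0.20). Of 14 tested members, 8 rose, 2 fell and 4 did not pass, also when adjusted over the list alone (Fisher's exact test, adjusted p = 4.4e-06), and the median log2 fold was 0.87, or 0.67 relative to all genes. The median difference of log2(FPKM + 1), 0.79, lay above that of all 10000 random lists. Of these calls, 6 rises and the fall of Cer1 were kept after trend removal, and the fall of Skil, named after its value was seen, was not.

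**Figure D2:**
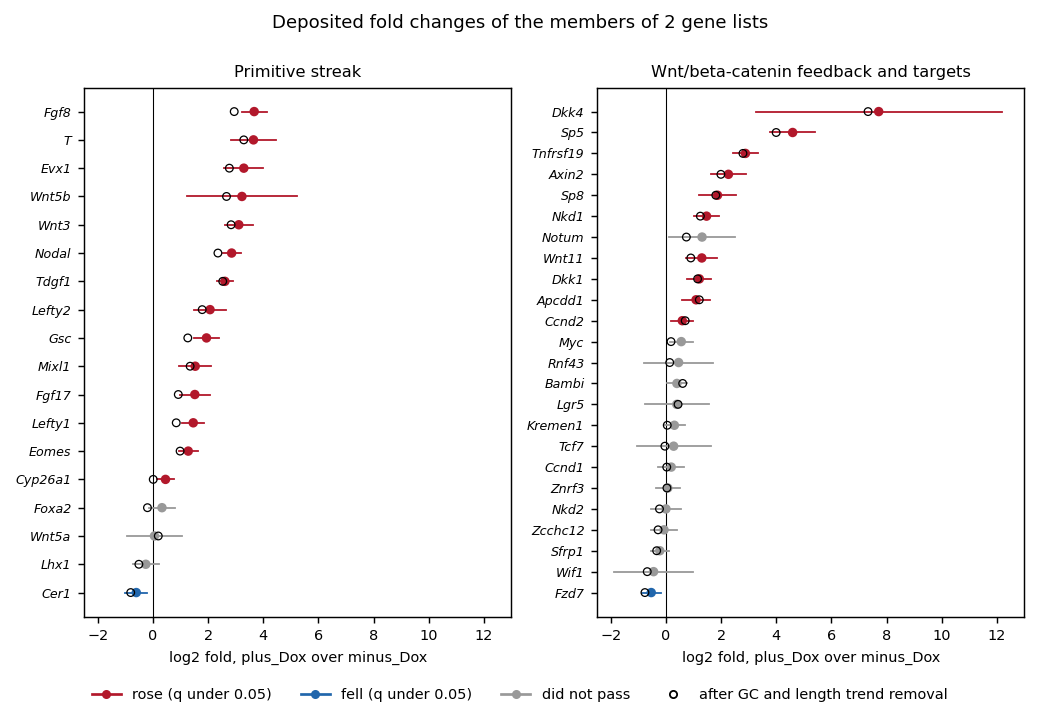
Deposited log2 fold of plus_Dox over minus_Dox for each tested member of 2 gene lists (filled points) with the 95% interval from the SE implied by the authors' statistic (bars), coloured by whether the gene rose, fell or did not pass a q-value of 0.05; open circles give the fold after removal of the GC and length trend. Of the 18 streak genes 14 lie on the side of higher expression and pass, and most open circles of these genes stay well above 0.

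Pluripotency genes did not move as a group. Nanog rose from 28.6 to 109.7 FPKM in the authors' deposited table (3.83-fold, log2 SE 0.19, q listed as 0), while Sox2 (56.2 to 30.9 FPKM, log2 fold -0.86, SE 0.17, q = 2.7e-05) and Fgf4 (9.95 to 5.58 FPKM, log2 fold -0.83, SE 0.19, q = 0.00032) fell. The Sox2 row spans chromosome 3 from 34003359 to 34581541 in mm9, far more than the single-exon gene, so it takes in other transcripts. Dppa5a rose from 363 to 524 FPKM in the authors' deposited table (log2 fold 0.53, SE 0.16, q = 0.012), and its log2 fold was 0.04 after trend removal, where the other 3 calls were kept. In all, 2 of 20 tested members of the naive list rose and 2 fell (Fisher's exact test, adjusted p = 0.54; 0.038 after trend removal).

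Of the formative and primed epiblast list, 16 genes were tested, 2 rose and 2 fell. In the authors' deposited table Fst, the activin antagonist follistatin, rose from 2.93 to 10.1 FPKM (3.43-fold, log2 SE 0.22), and the epiblast and neural factor gene Pou3f1 fell from 36.8 to 26.1 FPKM (log2 fold -0.49, SE 0.16, q = 0.024); both were kept after trend removal. Lin28b (log2 fold -0.59, SE 0.19, q = 0.024) and Utf1 (log2 fold 0.48, SE 0.16, q = 0.030) in the authors' deposited table were not kept, and Utf1 turned to -0.23. The list's median difference of log2(FPKM + 1), -0.10, lay below those of all 10000 random lists. Its median log2 fold was -0.11, or -0.31 relative to all genes, although the mean log2 fold was 0.06. The number of calls did not pass (Fisher's exact test, adjusted p = 0.32; 0.0016 after trend removal, with a rise of Fst and falls of Pou3f1, Sox3 and Zic2, the last 2 named after their values were seen). Of 15 tested neural ectoderm genes, Zic5 fell in the authors' deposited table (32.6 to 20.9 FPKM, log2 fold -0.64, SE 0.22, q = 0.035), which did not pass when adjusted over the list alone or, with a log2 fold of -0.70, after trend removal (q = 0.067), and none rose. The list's median log2 fold was -0.22. Its median difference of log2(FPKM + 1) was -0.027, at percentile 4.9 of random lists, and -0.11 after trend removal, at percentile 0.30.

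Few markers of later or extraembryonic tissues passed the test. In the definitive endoderm list, 4 of 13 tested genes rose and 1 fell (Fisher's exact test, adjusted p = 0.062; 0.00081 after trend removal, with 2 rises and 2 falls). The authors' deposited table gives Trh at 164 and 643 FPKM (3.91-fold, log2 SE 0.16) and Gsc, an organizer transcription factor gene, at 1.47 and 5.64 FPKM (3.83-fold, SE 0.24), both kept after trend removal, whereas Sox17 (log2 fold 0.67, SE 0.24, q = 0.043) and Sfrp5 (0.70, SE 0.20, q = 0.0073) were not kept. In the nascent and paraxial mesoderm list 3 of 15 rose, Snai1 (1.11 to 2.13 FPKM in the authors' deposited table, q = 0.0050), Cited1 (28.0 to 48.6 FPKM, q = 0.00041) and Pcdh8, named after its value was seen, and none was kept. Sox17 was the 1 rise among 15 haematopoietic and endothelial genes, and Evx1, kept after trend removal, the 1 rise among 8 tested posterior patterning genes. All 8 of the latter were higher in plus_Dox, with a median log2 fold of 0.96. That list's median difference of log2(FPKM + 1) stood at percentile 92.2 of random lists, and at 73.2 after trend removal. Extraembryonic endoderm showed 2 rises in 18 genes (Apoe, 590.0 to 1057 FPKM in the authors' deposited table, and Amn, 27.2 to 43.8 FPKM). Trophoblast showed 2 in 11 in the authors' deposited table (Krt8, 97.9 to 173 FPKM, and Krt18, 115 to 194 FPKM). Germ cells showed 1 rise in 8 (Ifitm3, 35.3 to 65.4 FPKM in the authors' deposited table) and 1 fall (Dazl, named after its value was seen). None of these calls in the 3 lists was kept after trend removal. The extraembryonic endoderm list then had 1 fall, and its median log2 fold went from 0.13 to -0.20. Its median difference of log2(FPKM + 1) went from percentile 25.65 to 0.02 of random lists. That of the definitive endoderm list went from percentile 83.04 to 3.64. Fibroblast markers were included because the stem cells had been grown on embryonic fibroblasts. Of 15 tested, 2 rose and were kept, Tagln (87.4 to 176 FPKM in the authors' deposited table, log2 fold 1.01, SE 0.18) and Acta2 (18.8 to 34.1 FPKM, log2 fold 0.86, SE 0.17). The Tagln row spans chromosome 9 from 45646662 to 45744141 in mm9, against a transcript of 1595 nt, so it may take in other transcripts. The fibroblast list's median stood at percentile 93.1, or 99.5 among the 5 members with at least 5 FPKM. None of these lists passed the test of excess calls (adjusted p from 0.062 to 1).

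**Figure D3:**
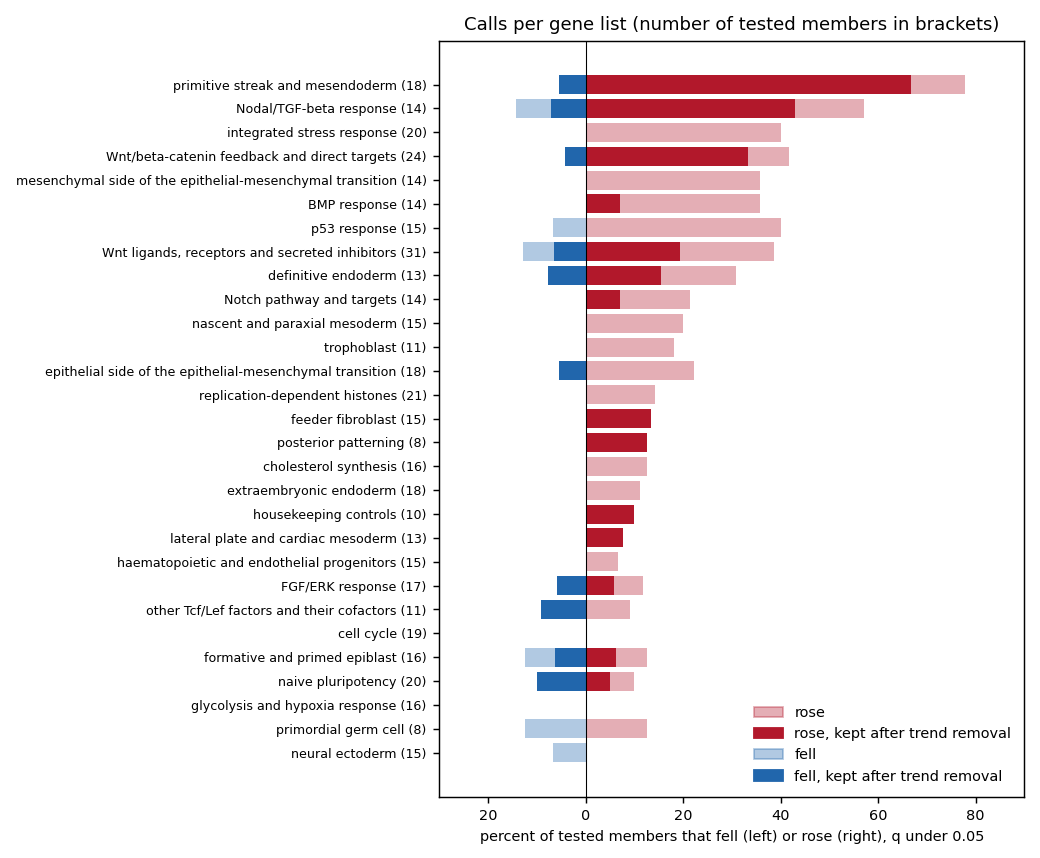
Percent of the tested members of each of 29 gene lists that rose (right) or fell (left) at a q-value of 0.05 in plus_Dox against minus_Dox, with the part kept after removal of the GC and length trend in full colour. The primitive streak list leads with 14 of 18 genes risen and 12 kept, and the 8 rises of the integrated stress response list are not kept.

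Smaller rises were seen in stress genes. The integrated stress response list had 8 rises and no fall among 20 tested genes (9 rises adjusted over the list alone). In the authors' deposited table Atf4, its central transcription factor gene, went from 89.1 to 139 FPKM (log2 fold 0.65, SE 0.16, q = 0.0015), Trib3 from 3.91 to 7.17 FPKM (0.88, SE 0.20) and Asns from 33.8 to 57.6 FPKM (0.77, SE 0.21). In the same authors' deposited table Chac1 went from 1.82 to 3.17 FPKM (0.80, SE 0.24) and Phgdh from 138 to 217 FPKM (0.65, SE 0.18). The excess passed as deposited (Fisher's exact test, adjusted p = 0.0076). After subtraction of the median shift Trib3 alone passed (Fisher's exact test, adjusted p = 1), and after trend removal none of the 8 was kept (adjusted p = 0.19), though the list's median still stood at percentile 99.2. The p53 response list had 6 rises and 1 fall among 15 genes (Fisher's exact test, adjusted p = 0.0061; 0.22 after the median shift and 1 after trend removal), while its median stood at percentile 49.6 of random lists. Its largest changes in the authors' deposited table were the fall of Trp53inp1 (25.8 to 12.2 FPKM, log2 fold -1.08, SE 0.21) and the rise of Bax (249 to 455 FPKM, 0.87, SE 0.18). The authors' deposited table also gives rises of Cdkn1a (11.7 to 20.2 FPKM, 0.78, SE 0.19), Bbc3 (17.4 to 28.9 FPKM, 0.73, SE 0.19) and Phlda3 (30.3 to 48.7 FPKM, 0.69, SE 0.20). None of the list's calls was kept.

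Of the other signalling and structural lists, 5 of 14 mesenchymal genes rose, led in the authors' deposited table by Snai1, Vim (41.5 to 76.4 FPKM), Twist1 (1.21 to 2.12 FPKM), Mmp14 (10.7 to 15.5 FPKM) and Itga5 (10.9 to 15.1 FPKM), and none was kept. Among 18 epithelial genes 4 rose, including Crb3 (48.2 to 78.4 FPKM in the authors' deposited table) and Cldn3 (8.04 to 12.6 FPKM, log2 fold 0.65, -0.056 after trend removal), and the tight junction gene Tjp1 fell (29.6 to 16.2 FPKM, log2 fold -0.87, SE 0.21), which alone was kept. BMP targets showed 5 rises in 14, with Smad7 (5.40 to 9.88 FPKM), Id3 (60.7 to 105 FPKM) and Smad6 (1.14 to 1.85 FPKM) in the authors' deposited table, and 1 was kept, that of Bmp7, named after its value was seen. Notch genes showed 3 rises in 14, of which Hes1 (14.8 to 36.7 FPKM in the authors' deposited table, 2.47-fold, log2 SE 0.24) was kept and Nrarp and Notch3 were not. Among 17 FGF/ERK response genes Fgf8 and Etv4 (13.3 to 24.9 FPKM in the authors' deposited table) rose and Fgf4 fell. Fgf8 and Fgf4 were kept after trend removal and Etv4 (0.91 to 0.37) was not, and the list's median went from percentile 14.1 to 0.44. None of these 5 lists passed the test of excess calls (adjusted p from 0.067 to 0.73).

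Cell cycle and glycolysis genes gave no call. Of 19 cell cycle genes, Pcna had 475 and 473 FPKM and Cdk1 198 and 237 FPKM in minus_Dox and plus_Dox in the authors' deposited table (q = 1.0 and 0.56), and of 16 glycolysis and hypoxia genes, Aldoa had 742 and 1019.7 FPKM and Pgk1 591 and 557 FPKM (q = 0.12 and 0.90). The glycolysis list's median log2 fold was -0.0059, or -0.21 relative to all genes. Its median difference of log2(FPKM + 1) was -0.0057, at percentile 1.2 of random lists, and -0.14 after trend removal, at percentile 0.56. Cholesterol synthesis showed 2 rises in 16 genes in the authors' deposited table (Mvk, 20.5 to 34.2 FPKM, and Fdps, 169 to 252 FPKM), neither of them kept. Replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, had 3 rises in 21 (Hist1h3c, Hist1h4b and Hist1h2ae), and a median log2 fold of 0.72. The median difference of log2(FPKM + 1), 0.25, stood at percentile 99.97 of random lists. None of the 3 rises was kept after trend removal, where the list's median stood at percentile 99.71. Hprt was the 1 call among 10 tested housekeeping genes and was kept after trend removal. The 13 mitochondrially encoded genes were not tested by the authors.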

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

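The removal of a GC and length trend was chosen after the fold changes were seen, as was the test of scaling on the primitive streak genes; the outcomes of the other tests had not been seen when their bounds were set.

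Among rows that the comparison does not use, 3 with a failed test and at least 5 FPKM had a plus_Dox value at least 2-fold the minus_Dox value in the authors' deposited table, against 0 with a change of that size in the other direction. They were Agpat3 (20.6 and 44.0 FPKM), Shf (4.56 and 12.2 FPKM) and AL672259.1 (listed at 0 and 28.7 FPKM). They drew attention as a signal outside the tested genes, were named after their values were seen, and have no test.

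More genes rose than fell. A bias tied to transcript composition could give this pattern. Of the authors' calls with known GC content and length, 12.5% passed again in the same direction after trend removal. On simulated data without a trend the removal left 112 of 113 calls and all 108 right ones. The simulated changes were drawn without regard to GC content or length, so that outcome was set in advance and does not bear on the 12.5%. The removal cannot separate a bias of library preparation from a real change in short, GC-rich transcripts, so part of the lost calls may be biological. Scaling of the FPKM between the groups stays open: subtraction of the median moves every fold by the same amount, so the share of rises after it (36.2%) follows from the step and does not bear on scaling. The biological difference that the design names, induced Lef1, stays among the open explanations for the excess.

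Primitive streak genes rose. Transcript composition is argued against as the whole cause, since 12 of 14 rises passed after trend removal. For Wnt5b the log2 fold went from 3.22 (SE 1.01) to 2.66 and lost its call through its wide SE, and for Cyp26a1 from 0.45 (SE 0.16) to 0.0063, so there the fold itself went. Scaling by the shift of 0.20 is argued against as the whole cause, since it leaves the list a median log2 fold of 1.53. That value follows from the deposited median of 1.73 by subtraction, so it shows only that this shift is too small to give the rise. An effect of doxycycline itself rather than the induced Lef1 cannot be told apart from that of Lef1, because 0 libraries had doxycycline without the transgene, so a rise driven by Lef1 stays a hypothesis.

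Integrated stress response genes rose. Transcript composition could give this pattern, as 0 of the 8 rises passed after trend removal. Of all 1574 authors' rises with known GC content and length only 169 were kept, so the loss is not particular to this list. The SE stayed as it was while the folds shrank, from 0.65 (SE 0.16) to 0.18 for Atf4 and from a median of 0.47 to 0.13 for the list. On the log2(FPKM + 1) scale the list's median difference stayed at percentile 99.2 of random lists after trend removal, and Slc7a11 (0.67) rose and Ddit4 (-0.70) fell as calls that were absent before, both named after their values were seen. An effect of doxycycline itself rather than the induced Lef1 cannot be told apart from one of Lef1, with 0 libraries given the drug without the transgene.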

How the results depend on the processing

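The trend removals and the restriction to genes with GC content and length were tests chosen after the data were examined; the other settings were fixed before. The count of 2210 changed genes (1626 higher, 584 lower) stayed within 1.5 times under a q-value threshold of 0.1, minima of 1 and 5 FPKM and restriction to genes with GC content and length. It was 1208 (901 higher, 307 lower) at a threshold of 0.01 and 491 (345 and 146) with a 2-fold minimum, both by construction. Median-ratio scaling gave 616 higher and 1085 lower, in a total of 1701. Removal of the GC and length trend left 366 (207 and 159), of the GC trend alone 491 (257 and 234) and of the length trend alone 903 (316 and 587); whether the trend comes from the libraries or the cells was not tested. The Lef1 log2 fold of 2.75 kept its direction under the 4 alternatives (2.55 to 2.74) and its call under the 2 of them with a test, scaling and trend removal. The number of lists with an excess of calls was 6, and 4 to 7 under the alternatives. Besides the changes given with each list, the mesenchymal list passed with a minimum of 1 FPKM (Fisher's exact test, adjusted p = 0.020), where fewer genes are tested. Lists with a median outside the middle 95% of random lists numbered 8, but 5 with random lists not matched on expression and 14 after trend removal; the cause was not tested. The percentile of the Wnt ligand and receptor list, 99.0, came inside the middle 95% with unmatched random lists (96.985), a minimum of 1 FPKM (95.65), a pseudocount of 0.1 (95.7) and median-ratio scaling (97.03), and turned to 24.8 with a minimum of 5 FPKM, where 10 of its 31 genes remain. With that minimum the Wnt target list came inside it (53.99) and the fibroblast (99.545) and trophoblast (97.68) lists went above it. Unmatched random lists brought the histone (96.63) and glycolysis (8.78) lists inside. After trend removal the Tcf/Lef partner (1.895), neural ectoderm (0.30), extraembryonic endoderm (0.02), epithelial (2.22) and FGF/ERK (0.44) lists went below it and the mesenchymal list above it (97.75, and 97.54 with a minimum of 1 FPKM). Of 91 named genes, 67 kept their direction and their side of the threshold under median-ratio scaling and 24 lost their call. Of 88 with GC content and length, 41 kept both after trend removal and 44 lost their call, while Utf1 and Cldn3 changed sign and lost their call, at -0.23 and -0.056, and Aldoa, without a call before or after, went from 0.46 to -0.13. Pseudocounts moved 33 named genes (pseudocount 1) and 5 (pseudocount 0.1) by more than their SE and turned none. No paired analysis was possible because the table gives 1 value per group; for the same reason no library could be left out, no other split of the libraries could be tried and the pseudocount alternative for gene counts was not run. The depth of the libraries is unknown, so what it limits was not computed.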

Other observations

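Interferon-inducible genes were higher in plus_Dox. They were chosen after their values were seen. The authors' deposited table gives Irgm1, an immunity-related GTPase gene, at 2.20 and 8.71 FPKM (3.97-fold, log2 SE 0.24), the guanylate-binding protein genes Gbp1 with a 3.25-fold rise from 0.460 FPKM (SE 0.26), Gbp2 at 0.703 and 2.19 FPKM (3.12-fold, SE 0.29) and Gbp3 at 0.230 and 1.10 FPKM (4.78-fold, SE 0.46). It also gives the chemokine gene Cxcl10 at 1.08 and 3.63 FPKM (3.36-fold, SE 0.42), the transcription factor gene Irf1 at 17.3 and 38.5 FPKM (2.22-fold, SE 0.22) and the immunoproteasome gene Psmb10 at 22.6 and 62.0 FPKM (2.74-fold, SE 0.20). These 7 of the 10 genes first noticed passed both as deposited and after trend removal. Of the other 3, Erap1 passed after trend removal alone and B2m and Ddx58 in neither.

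The hypothesis that an interferon response beyond the genes first noticed had risen was tested on 49 further interferon-inducible genes, written down before their values were looked at. Of the 37 with a test and known transcript composition, 10 rose and 1 fell in the authors' deposited table (Fisher's exact test, two-sided, p = 0.0051 for the number of calls), among them Bst2 (117 to 235 FPKM), Psmb8 (1.62 to 4.51 FPKM) and Igtp (2.67 to 4.86 FPKM). After trend removal their median log2 fold was 0.35, and their median difference of log2(FPKM + 1), 0.11, stood at percentile 99.99 of random lists of matched expression, in the direction of the hypothesis. No single gene of the 37 passed after trend removal, while 10 had an unadjusted p under 0.05 in the normal test, 8 of them higher, so a wider response may be present at a size that single genes do not show. Its origin was not tested.

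Other values are given without explanation. Pou5f1, a core pluripotency gene outside the naming rule, had 820.2 and 1510.2 FPKM in the authors' deposited table (log2 fold 0.88, SE 0.33, q = 0.055). Its log2 fold was 0.25 after trend removal. The row that joins the mitochondrial tRNA genes mt-Ta, mt-Tc, mt-Tn and mt-Ty, chosen after its value was seen, fell from 399 to 38.3 FPKM in that table (log2 fold -3.38, SE 0.24), and so did Lars2. Of 264 numbered Zfp genes with at least 1 FPKM, 13 rose and 37 fell in the authors' deposited table, with a median log2 fold of -0.14, and 6 fell and none rose after trend removal (median -0.07). Of 125 tested ribosomal protein pseudogenes, 26 rose and 1 fell in the authors' deposited table, with a median log2 fold of 0.94 that was 0.33 after trend removal in the 122 with known composition (3 rises, 3 falls). Among 19 ribosomal protein genes whose depth was too high for the authors' test, 15 were listed at 0 in plus_Dox alone and 0 in minus_Dox alone.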
